A study of Mus musculus with 6 samples.

How the data were processed

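Transcript levels were measured on Affymetrix GeneChip arrays for the whole mouse genome, which read each transcript with 1 or more probe sets of short oligonucleotides. Total RNA came from primary mouse myoblasts, with 3 arrays of control cells and 3 arrays of cells that carried a short hairpin RNA (shRNA) against LncMyoD. Groups and replicate numbers were taken from the sample labels, which call the replicates biological. Nothing in the labels says that they came from separate animals or cultures, so p-values measure the spread between these arrays, which may be technical.

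The deposited table holds 1 normalized log2 signal per probe set and array. The log2 scale was read from the values, which ran from 4.48 to 14.6, the range of log2 signals on this kind of array. All 6 arrays had the same median, 7.23, so the authors' normalization aligned the arrays on their medians or by a related method. The submitters' processing notes name PLIER and MAS5, programs that turn probe intensities into a signal, without saying what each was used for. Their versions, the background correction and any added offset are not given in the sources used here. No value lay below a log2 of 4, the level of an offset of 16. Scanner files and detection calls were not used here, so a low signal could not be told from background by a detection test. An array has no read depth; the number of arrays per group, 3, limits the precision. Of the columns of values, 0 were left without a sample.

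Probe sets were named through GEO's platform annotation. Of 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 were unnamed here, and no gene was named from a probe set with several. The gene identifiers of 34754 of those with 1 symbol were found in a table of mouse genes from assembly GRCm38.p6, and 0 symbols had to be updated. That table was used for names and for the order of neighbouring genes, and no coordinates are given because no genome build is named for the array values.

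The 64 Affymetrix control probe sets were left out first. The 40% of the remaining probe sets with the lowest mean over all 6 arrays (18015) were then left out, which kept those with a mean log2 signal of 6.50 or more. The 27022 tested probe sets include 4039 without a single gene name. Each gene was represented by its probe set with the highest mean over all arrays, using those ending in _x_at only where a gene had no other, which gave 12408 genes. Differences were tested on the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), as shRNA minus control without covariates. Adjusted p-values are Benjamini-Hochberg values over all probe sets tested, with a threshold of 0.05. Errors given after ± are SDs over n = 3 arrays, and SE is limma's standard error of the difference.

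The choices that follow were made before the data were examined, together with the filter, the test and the probe set that stands for a gene. A set of 19 gene lists with 422 members covered muscle genes, the cell cycle, insulin-like growth factor signalling, the interferon response and markers of other cell types. It also covered RNA-binding proteins of the IMP family, with mRNAs reported as clients of its member IMP2. Of these members, 17 had no named probe set here and are not analysed here, and 329 passed the filter. Each list was tested with limma's camera against the other genes, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 19 lists. Camera with an estimated correlation and limma's fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. The estimated correlation rests on 6 arrays, and its precision was not measured. Genes were named by a fixed rule with 3 parts, which gave 79 genes. The first part is a set of 11 genes of myogenesis, the cell cycle and the IMP list, of which 10 could be tested. The second is the 10 largest increases and the 10 largest decreases among genes past the threshold whose arrays did not overlap between the groups, leaving out symbols that are only clone or model names. The third is up to 3 members of each list with the smallest p past the threshold. A further 65 genes, named beside a count or in the closing section, were chosen after their values were seen.

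The ratio of 3' to 5' signal of the actin and GAPDH control probe sets, a sign of RNA integrity, was compared between the groups with a two-sided exact permutation test over the 20 assignments of arrays to groups. Its smallest possible p is 0.1. The calculations were tested on simulated data: values for the same 27022 probe sets, with 100 probe sets changed by 0.5 and 100 by 1 on the log2 scale. Of those, 73% and 94% were recovered with the right sign, and 6.70% of the probe sets called were false. The simulated noise was independent between probe sets and few of them changed, whereas 53.9% passed the threshold in the data. These rates therefore check the calculations and need not hold for the data. Other settings, fixed before the data were examined, changed the filter, the normalization between arrays, the variance model, array weights, the pairing by replicate number, the choice of probe sets and the set test, and left out each array in turn. Offsets before taking logs, also foreseen, apply to linear values and were not run, because the values are on a log scale. Scaling the arrays on the hybridization control spikes was added after the data were seen. The planned centring of each array on its median was done over the tested probe sets. That change was also made after the data were seen, because the medians over all probe sets were already identical.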

Results

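Primary myoblasts, the muscle precursor cells that fuse into myotubes in culture, were profiled on 6 arrays of 45101 probe sets each. In 3 samples the cells had received a lentiviral shRNA against LncMyoD, a long non-coding RNA reported to be transcribed from a site upstream of Myod1, and 3 samples were controls. The labels give an age of 21 days for every sample. They describe a growth medium and a low-serum differentiation medium without saying in which the profiled cells were kept, and they do not say what the controls received. Genes of differentiated muscle were bright in both groups. Of 46 tested sarcomere genes, 20 had a mean log2 signal above 13 over the 6 arrays. Mylpf stood at 14.47 in controls and 14.49 in shRNA samples, Tnnt2 at 14.16 and 14.13, and Acta1 at 14.07 and 13.98. Cultures of both groups therefore expressed such genes strongly, while their share of differentiated cells was not measured. No probe set could be matched to LncMyoD by its identifier, so the knockdown itself is not analysed here and the group names rest on the labels. Arrays of the same group correlated across probe sets at r = 0.996 to 0.997, and arrays of different groups at 0.987 to 0.990; probe sets are not independent replicates. No more than 0.00443% of values were identical in any pair of arrays.

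The comparison asks which transcripts differ when LncMyoD, studied as a regulator of muscle differentiation, is targeted. In the shRNA samples 28 of 46 tested sarcomere genes and 13 of 23 genes of muscle energy supply fell. Of 19 satellite cell genes and inhibitors of myogenesis 13 rose, as did 18 of 25 DNA replication genes. Each of these lists was called by limma's camera with a preset correlation, and none with an estimated correlation (adjusted p = 0.192 for the first pair, 0.647 and 0.542 for the others). Tcap, which caps titin at the Z-disc, fell from 11.25 ± 0.074 to 9.29 ± 0.044 (log2 signal, SD, n = 3), or 3.90-fold. Ckb, a creatine kinase, fell 3.97-fold, from 12.75 ± 0.032 to 10.76 ± 0.045. Pax7, a transcription factor of satellite cells, the muscle stem cells, rose 1.58-fold, from 11.40 ± 0.042 to 12.06 ± 0.097, and the replication licensing factor Cdt1 rose 2.40-fold, from 8.53 ± 0.075 to 9.79 ± 0.028. Myod1, the myogenic factor beside LncMyoD, was at 13.80 ± 0.074 in controls and 13.82 ± 0.064 in shRNA samples, a difference of 0.023 (SE 0.044, limma adjusted p = 0.688).

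In limma's test, 7258 of 12408 genes (58.5%) passed the threshold, of which 4426 were higher and 2832 lower in the shRNA samples. When each array was centred on its median over the tested probe sets, 3627 were higher and 3663 lower, so the balance of directions depended on the scaling. Most differences were small, with a median size of 0.35 on the log2 scale among the genes that passed, and 468 genes differed at least 2-fold (270 higher, 198 lower). Of all tested probe sets, 14566 of 27022 (53.9%) passed, 8214 higher and 6352 lower. The 2 groups' arrays did not overlap in 64.8% of genes, against 10% by chance, and the median SD between replicates was 0.068 in controls and 0.058 in shRNA samples. Among the genes that passed, 3707 had another tested probe set, and in 258 such a probe set had changed the opposite way. Among the genes named as changed from the 19 lists and the largest differences, another probe set did not pass in Acss2, Akt2, Ccnd3, Cdc45, Chrng, Fn1, Jam2, Mb, Mef2d, Myh4, Rbl1, Sdc3, Stat2 and Tpm3, and 2 others did not in Eif4a1 and Smyd1.

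The 3' to 5' signal of the control probe sets, a sign of RNA integrity, also ran with the groups. For actin the log2 ratio was 0.51 ± 0.018 in controls and 0.55 ± 0.017 in shRNA samples (n = 3 each), and for GAPDH 0.14 ± 0.045 and 0.23 ± 0.038. Both had an exact permutation p = 0.1, the smallest that 20 assignments allow. These differences of 0.044 and 0.085 stand beside every gene group described here.

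Rasal1, a GTPase-activating protein for Ras, had the largest measured increase, 3.20 on the log2 scale, from 5.48 ± 0.18 to 8.68 ± 0.28 (limma adjusted p = 3.81e-09). Rnf182, Cntfr, Myzap, Nrcam, Fndc10, Nr4a1, Pde4b, Inhbb and Gtse1 followed with increases of 2.50 down to 2.13 on the log2 scale. Cntfr binds ciliary neurotrophic factor, Nr4a1 is a nuclear receptor of the immediate-early class, Pde4b breaks down cyclic AMP and Inhbb encodes a subunit of activin B. Mfap4, a protein of extracellular microfibrils, had the largest measured decrease, -2.83, from 8.62 ± 0.094 to 5.79 ± 0.085 (limma adjusted p = 9.95e-10). Tnfrsf13c, Ctsw, Muc15, Ctrb1, Acss2, Pde2a, Afap1l1, Fyb and Ckb followed, with changes of -2.50 to -1.99. Acss2 makes acetyl-CoA from acetate, Pde2a breaks down cyclic nucleotides and Ctrb1 is chymotrypsinogen. The control means of Rasal1, Cntfr, Nrcam and Gtse1, and the shRNA means of Mfap4, Tnfrsf13c, Ctsw and Muc15, lay below 6.50, among the signals of the probe sets left out as low. Whether these means lay above background was not tested, so the sizes and ranks of these 8 changes are not settled. Each of these 20 genes passed the threshold in every setting that tested it.

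Of 19 lists, camera with the preset correlation called 3 lower and 3 higher than other genes. With an estimated correlation it called 0, with 3 at an unadjusted p under 0.05, while fry called 14. Splits of the arrays that mix the groups also called 5 of the 6 lists called with the preset correlation, sarcomere genes in 8 of the 9 other splits, calcium handling and energy supply in 4 each, and satellite cell and DNA replication genes in 2 each. Each such split keeps most arrays of a group on the same side, so part of the real difference stays in it. These calls therefore do not measure how often a list is called by chance. Adjusted over the list alone, the counts of members that rose and fell were those given here except in 5 lists. They became 5 and 16 for calcium handling, 7 and 1 for the IMP list, 4 and 9 for the extracellular matrix, 1 and 0 for leukocytes and 0 and 0 for endothelium.

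Sarcomere genes, which build the contractile unit, fell in 28 of 46 tested cases, with 5 that rose and 13 not past the threshold. Their median change was -0.16 (limma camera adjusted p = 4.59e-07, and adjusted p = 0.192 with an estimated correlation). Besides Tcap, the Z-disc LIM protein Csrp3 fell by 1.44 (SE 0.049) and Lmod2, an actin filament nucleator, fell by 1.26 (SE 0.054). Those that rose were Tpm3 (0.42), Actn3 (0.48) and the myosin heavy chains Myh2 (0.49), Myh4 (0.28) and Myh8 (0.27). The call of Myh4 was lost without control 2 (0.21, limma adjusted p = 0.149), without shRNA array 1 (0.22, 0.138), 2 (0.31, 0.0540) or 3 (0.31, 0.0587). Changes were smaller among bright transcripts: the 26 sarcomere genes with a mean signal below 13 had a median of -0.58, and 18 fell and 5 rose. The 20 above 13 had a median of -0.078, and 10 fell and 0 rose in limma's test.

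**Figure D1:**
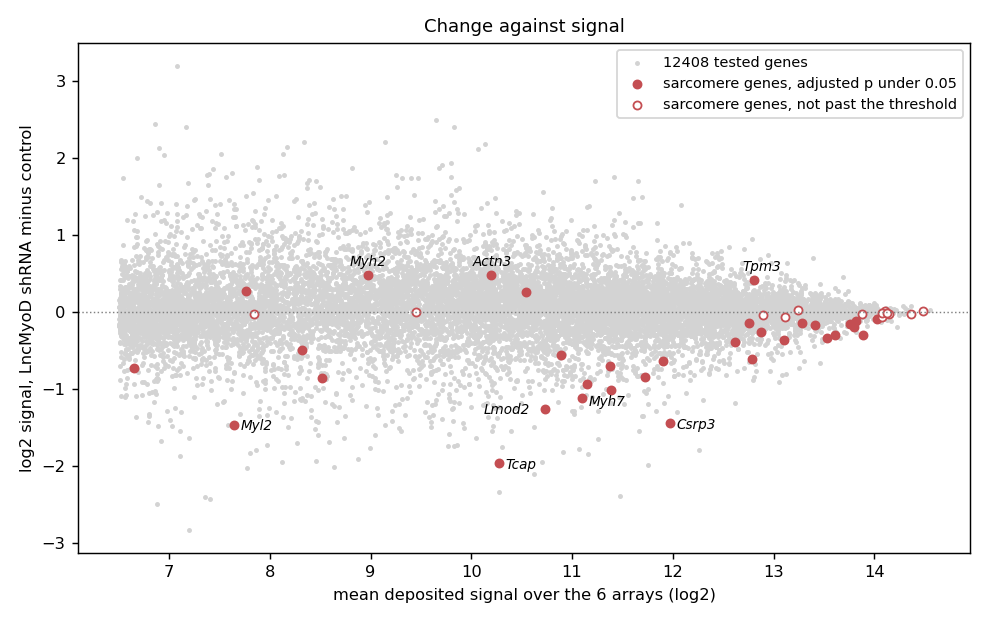
Change between shRNA and control (log2, vertical axis) against the mean log2 signal over the 6 arrays (horizontal axis) for 12408 tested genes (grey) and 46 sarcomere genes, filled where limma's adjusted p was under 0.05. The spread of changes narrows above a signal of 13, where sarcomere genes had a median of -0.078, against -0.58 below it.

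Genes of muscle energy supply fell in 13 of 23 cases, with 4 that rose and 6 not past the threshold, and a median of -0.35 (limma camera adjusted p = 0.00101, and adjusted p = 0.192 with an estimated correlation). The muscle creatine kinase Ckm fell by 1.41 (SE 0.061), 2.66-fold, and myoglobin, Mb, fell by 0.80 (SE 0.034). Ppargc1a, a coactivator of mitochondrial genes, rose by 0.97 (SE 0.056), with smaller increases of Pdk4 (0.18), Cox8b (0.17) and the lactate dehydrogenase subunit Ldhb (0.12). The call of Ldhb was lost without control 3 (0.10, limma adjusted p = 0.0633) or shRNA array 2 (0.11, 0.0766), and under both centring (0.059) and spike scaling (0.11).

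In the calcium handling and neuromuscular junction list 15 of 25 genes fell, 4 rose and 6 did not pass. The median was -0.15 (limma camera adjusted p = 0.00163, and adjusted p = 0.192 with an estimated correlation). The calcium buffer Pvalb fell 3.31-fold, from 8.84 ± 0.080 to 7.11 ± 0.14. Srl and Casq2, proteins of the sarcoplasmic reticulum, fell by 0.60 (SE 0.039) and 0.52 (SE 0.036). The 4 that rose were the acetylcholine receptor subunits Chrnd (0.26) and Chrng (0.12), the sarcoplasmic reticulum protein Jsrp1 (0.21) and the calcium pump inhibitor Sln (0.31). Chrng was no longer past the threshold without control 3 (0.099, limma adjusted p = 0.0572) or with the arrays centred (0.058, 0.147). Sln was not past it without control 2 (0.32, limma adjusted p = 0.0680) or 3 (0.23, 0.138), nor without shRNA array 1 (0.32, 0.0608) or 2 (0.26, 0.129).

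Satellite cell genes and inhibitors of myogenesis rose in 13 of 19 cases, with 2 that fell and 4 not past the threshold. The median was 0.41 (limma camera adjusted p = 0.00624, and adjusted p = 0.647 with an estimated correlation). The surface proteoglycan Sdc4 rose by 0.95 (SE 0.046), the growth factor receptor Fgfr1 by 0.78 (SE 0.050) and Pax7 by 0.66 (SE 0.051), with both of its probe sets past the threshold. Pax3 (0.94) and Twist1 (1.11), an inhibitor of myogenic factors, also rose. The 2 that fell were Sdc3 (-0.37) and the hepatocyte growth factor receptor Met (-0.31).

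DNA replication genes rose in 18 of 25 cases, with 3 that fell and 4 not past the threshold, and a median of 0.32 (limma camera adjusted p = 0.00646, and adjusted p = 0.542 with an estimated correlation). The primase subunit Prim1 rose 2.42-fold, from 9.29 ± 0.048 to 10.57 ± 0.031, and the helicase subunit Mcm2 rose by 0.99 (SE 0.060). The 3 that fell were Rrm2 (-0.47), Fen1 (-0.48) and Cdc45 (-0.29), the last not past the threshold with its probe sets averaged (-0.16, limma adjusted p = 0.124). Mitosis genes as a list were not called (camera adjusted p = 0.733, limma): of 19, 5 rose, 3 fell and 11 did not pass, with a median of 0.10. Hmmr (0.95), Tpx2 (0.82), Cdk1 (0.58), Cdc20 (0.53) and Plk1 (0.40) rose, whereas Top2a (-0.72), Kif11 (-0.52) and Birc5 (-0.27) fell. The shRNA mean of Kif11, 6.48, also lay below 6.50. Birc5 lost its call without control 1 (-0.22, limma adjusted p = 0.0924) or 2 (-0.28, 0.0665), or shRNA array 2 (-0.17, 0.164).

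Among cell cycle exit genes 6 of 17 rose, 2 fell and 9 did not pass, with a median of 0.089 (limma camera adjusted p = 0.291). The antiproliferative gene Btg2 rose 2.08-fold, Rbl1, a relative of the retinoblastoma protein, rose 2.09-fold and Ccnd3 rose by 0.44 (SE 0.048). The cell cycle inhibitors Cdkn2d (-0.54) and Cdkn1c (-0.33) fell, the latter not without control 2 (-0.32, limma adjusted p = 0.0529) or shRNA array 2 (-0.29, 0.0639). Cdkn1a, a cell cycle inhibitor induced in differentiating myoblasts, stood at 14.18 in both groups (limma adjusted p = 0.995). Ccnd1, cyclin D1, rose 1.83-fold, from 10.85 ± 0.10 to 11.72 ± 0.066 (limma adjusted p = 5.99e-08), with all 3 of its probe sets past the threshold.

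Muscle regulatory factors moved both ways, and the list was not called (limma camera adjusted p = 0.401). Of 13 genes 4 rose, 6 fell and 3 did not pass, and the median (-0.047) and the mean (0.048) differed in sign. Eya1 (1.29, SE 0.063), Six4 (0.46), Myf6 (0.70, SE 0.12) and Myf5 (0.62, SE 0.11) rose. Tead4 (-0.85, SE 0.063), Klf5 (-0.60, SE 0.039), Smyd1 (-0.34), Mef2c (-0.26, SE 0.038), Mef2d (-0.22) and Myog fell. All 5 probe sets of Mef2c fell, by 0.26 on the brightest and by 0.58 on the dimmest. Myog, myogenin, fell by 0.13 (SE 0.039) from 14.13 ± 0.060 (limma adjusted p = 0.0115), a call lost without a variance trend (adjusted p = 0.0799). Myod1, Myog, Mef2c and Cdkn1a all lay above a signal of 13 on the probe sets that stood for them. A dimmer probe set of Myod1, at 11.46 in controls and 11.34 in shRNA samples, differed by -0.12 (SE 0.060, limma adjusted p = 0.111). In 348 genes with a probe set above 13 and another between 9 and 12, the dimmer changed more by a median of 0.12, against 0.015 in 1552 pairs of probe sets that were both dim.

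**Figure D2:**
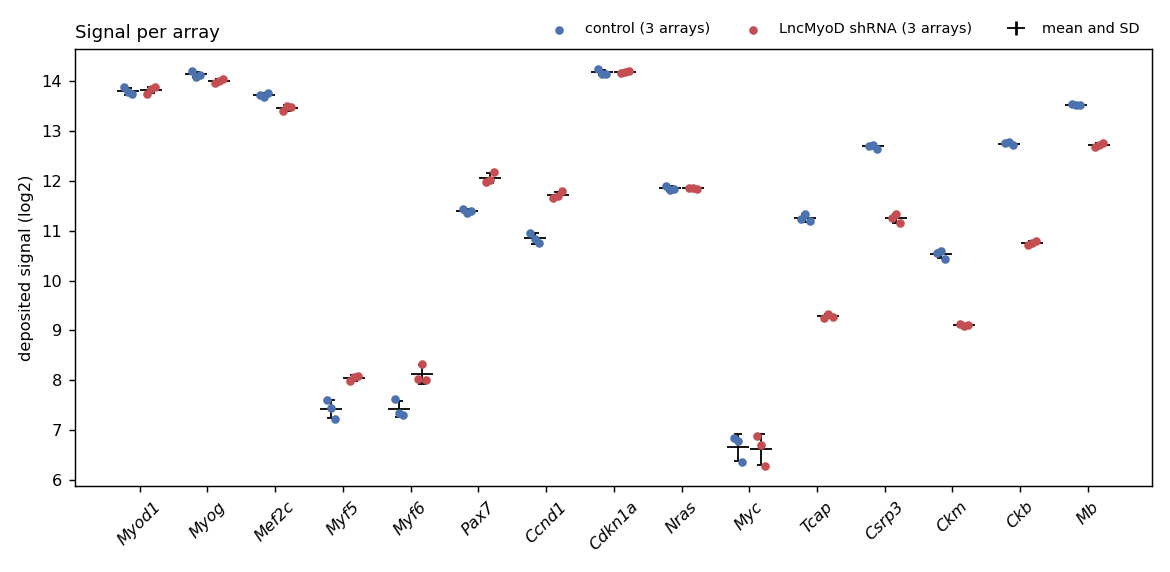
Log2 signal (vertical axis) of 15 genes (horizontal axis) on each of the 3 control and 3 LncMyoD shRNA arrays (points), with group means and SDs (bars). Tcap, Csrp3, Ckm, Ckb and Mb lie lower in every shRNA array, whereas Myod1 and Cdkn1a overlap between the groups.

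In the myoblast fusion and adhesion list 9 of 23 genes rose, 8 fell and 6 did not pass (median -0.035, limma camera adjusted p = 0.491). The adhesion molecule Jam2 fell 2.43-fold, and the fusion proteins Mymk (-0.24) and Mymx (-0.29) fell. Dock1 (0.62, SE 0.046) and Cdh15, M-cadherin (0.40, SE 0.037), rose.

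The IMP family of RNA-binding proteins and mRNAs reported as clients of its member IMP2 were followed because the study's title ties LncMyoD to this family. The arrays measure transcript levels, not translation. Of 13 tested genes 7 rose, 0 fell and 6 did not pass, with a median of 0.089 (limma camera adjusted p = 0.211). Tested members of the family itself were found both among the genes that rose and among those that did not pass. Not every member of the family could be tested, and IMP2 itself is not analysed here, so the list rests mainly on the reported clients. Besides Ccnd1, Cd44 (0.84, SE 0.066) and Igf1r (0.41, SE 0.046) rose, although 1 of the 4 probe sets of Igf1r fell (-0.32). Nras was at 11.85 in both groups (limma adjusted p = 0.997), but its other 2 probe sets fell by 0.31 (adjusted p = 0.000841) and 0.14 (adjusted p = 0.0175). Myc stood near the lower end of tested signals, at 6.66 ± 0.27 and 6.62 ± 0.31 (limma adjusted p = 0.868).

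Insulin-like growth factor signalling genes were not called as a list (median 0.080, limma camera adjusted p = 0.586), with 6 of 17 rising, 2 falling and 9 not past the threshold. Irs2, an adaptor of the insulin receptor, rose 2.74-fold and Igfbp3 rose by 0.58 (SE 0.052). Irs1 (-0.18) and Akt2 (-0.23) fell, but Akt2 stood at 0.13 (limma adjusted p = 0.140) when probe sets open to cross-hybridization, ending in _x_at or _s_at, were left out. Among ribosome biogenesis and MYC-responsive genes 10 of 28 rose, 4 fell and 14 did not pass, with a median of 0.045 (limma camera adjusted p = 0.733), or -0.019 with the arrays centred (limma camera adjusted p = 0.927). Eif4ebp1 (0.49, SE 0.060) and Nop56 (0.28, SE 0.044) rose, and Eif4a1 fell by 0.26 (SE 0.036), but its other 2 probe sets stood at -0.018 (limma adjusted p = 0.797) and -0.022 (0.661). Smaller decreases of Rrp9 (-0.23), Ldha (-0.096) and Ncl (-0.092) depended on single arrays. Rrp9 missed the threshold without shRNA array 3 (-0.19, limma adjusted p = 0.0517), and Ldha without control 1 (-0.079, 0.0576) or shRNA array 2 (-0.10, 0.0585) or 3 (-0.095, 0.0569). Ncl missed it without any 1 array (changes of -0.11 to -0.074, limma adjusted p of 0.0573 to 0.129).

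Interferon response genes rose in 10 of 14 tested cases, with 2 that fell, Stat2 (-0.34) and Rtp4 (-0.44, with an shRNA mean of 6.43, below 6.50), and 2 not past the threshold. The median was 0.48 (limma camera adjusted p = 0.0414, and adjusted p = 0.381 with an estimated correlation). The double-stranded RNA sensors Ifih1 and Ddx58 rose 2.49-fold and 1.80-fold, and Bst2, tetherin, rose by 0.74 (SE 0.052). The list's call ended without control 1 (0.48, limma camera adjusted p = 0.0640) or shRNA array 1 (0.48, 0.0565). It also ended with array weights (0.0576), a stricter filter on low signals (0.0933) or without probe sets ending in _x_at or _s_at (0.0580).

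Markers of other cell types were followed as a measure of what else the cultures held. Of the listed markers 15 of 24 were tested for fibroblasts and matrix, 8 of 16 for leukocytes and 4 of 14 for endothelium. For adipocytes, smooth muscle and glia 5 of 12, 10 of 12 and 5 of 11 were tested. The remaining markers had too low a mean signal or no named probe set here. Camera with the preset correlation called none of these marker lists when all 6 arrays entered and 1 probe set stood for each gene. Fibroblast and extracellular matrix genes had a median of -0.42 (limma camera adjusted p = 0.0929), with 8 of 15 falling, 4 rising and 3 not past the threshold. Loxl1 (-0.84, SE 0.062), Col5a1 (-0.66, SE 0.049) and Col5a2 (-0.54, SE 0.041) fell, whereas Pdgfra (0.89), Mgp (0.44), Lox (0.33) and Fn1 (0.13) rose. This list was called lower with probe sets averaged (-0.24, limma camera adjusted p = 0.0443) and without shRNA array 1 (-0.24, 0.0499). With an estimated correlation and 1 probe set per gene its camera adjusted p was 0.640. Lox missed the threshold without shRNA array 1 (0.27, limma adjusted p = 0.0526). Fn1 missed it without control 2 (0.11, limma adjusted p = 0.101) or 3 (0.12, 0.0673) or shRNA array 3 (0.10, 0.0964), and with the arrays centred (0.063).

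Of 8 leukocyte markers 2 rose and 0 fell in limma's test, with 6 not past the threshold; the median was -0.087 and the mean 0.064 (camera adjusted p = 0.733). Cd14 rose from 6.12 ± 0.23 to 7.19 ± 0.14 (limma adjusted p = 3.26e-05), and Cd68 rose from 6.40 to 6.73 (limma adjusted p = 0.0331). Both control means lay below 6.50, among the signals of the probe sets left out as low. The call of Cd68 was lost without control 2 (0.32, limma adjusted p = 0.0916) or 3 (0.28, 0.119), without shRNA array 1 (0.33, 0.0606), 2 (0.32, 0.0791) or 3 (0.35, 0.0656), and with centring (0.27) or spike scaling (0.32). Of 4 endothelial markers Erg fell (-0.23, SE 0.080) and 3 did not pass (median -0.040, limma camera adjusted p = 0.656). Erg did not pass without control 2 (-0.22, limma adjusted p = 0.0788) or shRNA array 1 (-0.17, 0.135). Adipocyte markers had 2 that rose, Cebpa (2.85-fold) and Lpl (2.41-fold), 1 that fell, Dgat2 (2.31-fold), and 2 not past the threshold (median 0.18, limma camera adjusted p = 0.733).

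Of 10 smooth muscle and pericyte markers, Mcam (0.72, SE 0.064) and Notch3 (0.41) rose, Tagln (-0.75, SE 0.053) and Smtn (-0.45, SE 0.052) fell, and 6 did not pass. Their median was 0.032, their camera direction was down (limma camera adjusted p = 0.733), and the median was -0.032 with the arrays centred and -0.0054 with quantile normalization. Of 5 glial markers the receptor Erbb3, which myoblasts also express, fell by 0.82 (SE 0.036) and Pmp22 by 0.24 (SE 0.044), with 3 not past the threshold. The glial list had a median of -0.099 (limma camera adjusted p = 0.113) and was called lower with probe sets averaged (-0.24, adjusted p = 0.0309). With an estimated correlation and 1 probe set per gene its camera adjusted p was 0.537.

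**Figure D3:**
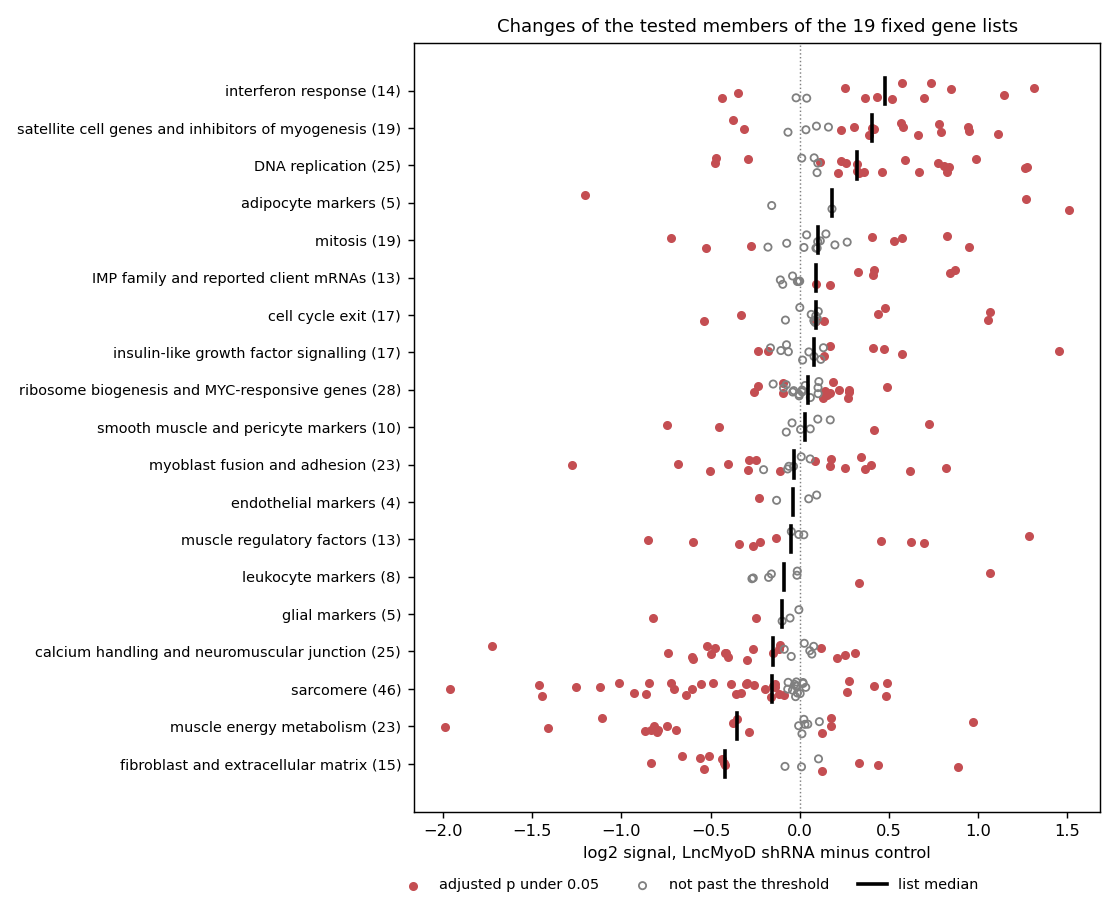
Change between shRNA and control (log2, horizontal axis) of every tested member of the 19 gene lists (vertical axis, number tested in brackets), filled where limma's adjusted p was under 0.05, with the list median as a bar. Medians run from -0.42 for the extracellular matrix to 0.48 for the interferon response, and most lists hold members on both sides of 0; the medians of the ribosome and smooth muscle lists fall below 0 with the arrays centred.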

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

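Spike scaling was chosen after the data were seen; the other settings were planned. The number of genes past the threshold ran from 6248 to 7638 over 16 settings and from 6426 to 7257 with any 1 array left out. Of the 7258 genes, 84.1% to 98.7% kept their call and direction. Both 6248 and 84.1% came from the stricter filter, which tested 9450 genes instead of 12408. A gene not tested there is counted as not kept. No count of genes past the threshold moved by over 1.5 times. Of the 79 genes named by rule, 72 kept their direction and side of the threshold in every setting that tested them, as did 52 of the 65 named afterwards. Lists shifted were 6 with the preset correlation, 0 with an estimated correlation and 14 with fry.

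With an estimated correlation the calls ended for sarcomere (-0.16, adjusted p = 0.192), calcium handling (-0.15, 0.192), energy metabolism (-0.35, 0.192), satellite cell (0.41, 0.647), DNA replication (0.32, 0.542) and interferon (0.48, 0.381), in limma's camera; the medians stay as they were, because that setting alters the test alone. Over all settings, fry included, the adjusted p of these lists ran from 1.04e-09, 8.80e-05, 1.19e-06, 0.000341, 0.000529 and 0.000178 up to those values. The low ends for calcium handling, DNA replication and interferon genes came from fry, and the others from camera. Limma's fry, which does not compare a list with other genes, also called adipocyte (0.18), cell cycle exit (0.089), extracellular matrix (-0.42), glial (-0.099), IMP (0.089), insulin-like growth factor (0.080), fusion (-0.035) and ribosome (0.045) genes. The interferon call ended with array weights (0.50), without the lowest 60% of probe sets (0.44) and without _x_at and _s_at probe sets (0.48), and its median ran from 0.41 to 0.49 with 1 array left out (adjusted p of 0.0216 to 0.0640). The extracellular matrix list was called with probe sets averaged (-0.24), and ran from -0.46 to -0.24 with 1 array left out (adjusted p of 0.0499 to 0.127). Over all settings adjusted p was 0.0103 (fry) to 0.640. Glial genes were called with probe sets averaged (-0.24), with adjusted p 0.00172 (fry) to 0.537 in all settings.

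Medians of lists not called changed sign: adipocyte (-0.16) and fusion (0.0084) without the lowest 60%, endothelial with probe sets averaged (0.054) and without a filter (0.017), and ribosome with centred arrays (-0.019). Smooth muscle did so with centred arrays (-0.032), probe sets averaged (-0.036) and quantile normalization (-0.0054). Genes that had not passed also changed sign. Cdkn1a did so with centring (-0.064), spike scaling (-0.0098), probe sets averaged (-0.0018) and quantile normalization (-0.0056), and ran from -0.015 to 0.030 with 1 array left out. Myod1 did so with centring (-0.041) and probe sets averaged (-0.048), and ran from -0.0094 to 0.063. Nras did so with array weights (0.020), ran from -0.023 to 0.026, and was called lower with probe sets averaged (-0.15, limma adjusted p = 0.0106). Myc ran from -0.19 to 0.13. Adjusted p over all settings ran from 0.000143 to 0.0799 for Myog and from 0.0106 to 0.998 for Nras. It ran up to 0.119 for Cd68, 0.135 for Erg and 0.620 for Myh4. Calls of members near the threshold also ended without a variance trend (Birc5, Chrng, Fn1, Ldha, Ldhb, Ncl), without a filter (Myh4, Sln, Ncl), with spike scaling (Chrng, Fn1, Ldhb, Myh4, Ncl), with centring (Chrng, Fn1, Ldhb, Myh4, Sln), with probe sets averaged (Akt2, Cdc45, Fn1, Myh4), with quantile normalization (Myh4) and with array weights (Ncl). Akt2 turned to 0.13 without _x_at and _s_at probe sets, which leaves another probe set to stand for it. The cause of the other changes was not tested.

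Replicate numbers are shared between the groups, but the labels do not say that they pair the arrays, so the main test was set beforehand without pairs. Arrays with the same number also did not deviate together (correlations of -0.13, -0.062 and 0.031). With the replicate number as a block, 6808 genes passed, and among named genes the calls of Fn1, Ldha and Ncl ended. How far background limits the dimmest genes was not measured, because detection calls were not used here. With no filter 7346 of 18193 genes passed (40.4%), and above the stricter filter 6248 of 9450 (66.1%).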

Other observations

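Of the tests in this part, quantile normalization, the splits of the arrays and the comparison of bright with dim probe sets were set before their results were seen; the gene groups chosen here and all other tests were chosen afterwards. Genes of sterol synthesis were noticed because Acss2 and Hsd17b7 were among the strongest decreases. All 18 other tested genes of the pathway and its regulation fell, with a median of -0.35. Tm7sf2 (-0.82), Fdft1 (-0.77) and Nsdhl (-0.72), enzymes on the way from farnesyl diphosphate to cholesterol, fell most. The group was lower than other genes by limma's camera (adjusted p = 3.36e-09, and adjusted p = 0.0837 with an estimated correlation), and 13 to 18 of its genes fell under the 16 settings. Chaperones and folding enzymes of the endoplasmic reticulum were noticed through Sdf2l1 and Pdia4. Of 19 others 17 fell, among them Manf (-1.30), Creld2 (-0.88), Pdia6 (-0.83), Hspa5, the chaperone BiP (-0.72), and the stress transcription factor Xbp1 (-0.50). Edem1 rose (0.32, with its other probe set at 0.024) and 1 did not pass. Their median was -0.45 (limma camera adjusted p = 8.82e-10, and adjusted p = 0.111 with an estimated correlation).

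Immediate-early genes, transcription factors and regulators that respond to growth factors within minutes, were noticed through Nr4a1, Nr4a3 (1.94, with its other probe set at -0.048) and Fosb. Of 17 others 12 rose, 1 fell (Klf4, -0.37) and 4 did not pass. Fos rose 3.07-fold, from 9.07 ± 0.18 to 10.69 ± 0.11, and Atf3 (0.96), Egr1 (0.83) and Junb (0.61) rose. The median was 0.54 (limma camera adjusted p = 0.000828, and adjusted p = 0.186 with an estimated correlation). Splits of the arrays that mix the groups also called these groups, in 9, 9 and 6 of the 9 other splits, but with medians of at most 0.13, 0.23 and 0.27 in size. Because such splits keep part of the real difference, they cannot tell whether chance gives these calls. That transcripts of sterol synthesis and folding genes were lower as groups, and those of immediate-early genes higher, is a hypothesis, found and tested on the same arrays.

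Of the tested probe sets 53.9% passed the threshold, which may be technical. Against a difference in hybridization or scanning stood the 43 spiked control probe sets, whose median difference was 0.178 times that of probe sets of the same signal (95% interval 0.113 to 0.225). Limma called 0 of them, and 2 of 60 control probe sets, mouse controls included, had an unadjusted p under 0.05. After quantile normalization 15021 probe sets passed, compared with 14566. The deposited arrays were already aligned and the authors' scaling was not undone, so this count cannot speak against an effect of that scaling. A batch of culture, infection or RNA preparation that coincides with the groups cannot be told apart from the shRNA, because the labels give 0 batches that hold both groups.

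The 10 splits of the arrays into 3 and 3 are too few for a share under 0.05: 1 split, the real one, gave as many genes (7258, highest other 1) and as many probe sets (14566, highest other 1), and 2 gave as many shifted lists (6, highest other 7, with control 1 beside shRNA arrays 1 and 3). Of the lists called in the real split, camera also called sarcomere genes in 8 of the 9 other splits (lowest unadjusted p = 6.90e-07, real 2.42e-08), calcium handling and energy metabolism in 4 each, satellite cell and DNA replication genes in 2 each and interferon genes in 0, although their lowest other p, 0.0117, was below the real 0.0131. The medians of these 6 lists in the other splits were at most 0.075, 0.089, 0.16, 0.23, 0.19 and 0.19 in size, compared with 0.16, 0.15, 0.35, 0.41, 0.32 and 0.48 in the real split. Of the lists not called in the real split, mitosis, cell cycle exit and extracellular matrix genes were called in 2 other splits each and glial markers in 1. The 9 other splits keep part of the real difference, so their calls and medians do not show what chance alone gives.

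Sarcomere genes fell unevenly, with large decreases in Tcap and Csrp3 and small ones among the brightest transcripts. A lower share of differentiated cells was taken to lower every member, yet 5 members below a signal of 13 rose. This rule was set after those increases were seen, so it cannot decide on that cause. Whether less differentiated cells also expressed some members was not measured. The call of Myh4 depended on single arrays, those of Tpm3, Actn3, Myh2 and Myh8 held in every setting, and another probe set of Tpm3 did not pass. Compression of differences at the bright end of the scale is a candidate explanation for part of the pattern. In genes read by a bright and a dim probe set, the dimmer showed the larger change by 0.106 more than in pairs of dim probe sets (95% interval 0.0767 to 0.125). A change in the set of sarcomere genes the cells expressed stays open as well.

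Otog, an inner ear gene that neighbours Myod1, fell 2.91-fold, from 10.07 ± 0.040 to 8.53 ± 0.063 (n = 3, limma adjusted p = 2.45e-09), whereas Myod1 did not pass. A change shared by the genes around Myod1 was not seen. The 10 nearest tested genes on each side had a median change of 0.168 in size, below 0.253, the limit set for the test from 10000 random sets of as many genes. Of these 20 genes 10 passed limma's threshold, compared with 58.5% of all genes, and 0 changed 2-fold. Whether its probe set reads another transcript of this region, where LncMyoD is reported to lie, cannot be told apart from a fall of Otog itself, because the gene has 1 probe set.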
